A study of Homo sapiens with 6 samples.

How the data were processed

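Bulk RNA-seq was read from 6 libraries of Capan-1 cells, 3 made from cells with an empty vector and 3 from cells overexpressing TRIM22. Per the labels' protocols, messenger RNA was captured on oligo(dT) beads from total RNA extracted with Trizol, and libraries followed the standard Illumina procedure. How TRIM22 was introduced, the culture density at harvest and the read length are not given in the sources used here.

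Per the file headers, each library's deposited file gave a count, a CPM value and an RPKM value for each Ensembl gene. The submitters' processing notes name bcl2fastq, STAR 2.0.4b, Subread and featureCounts 1.45, with no parameters. The strand setting and the rule for reads that match several places are not given in the sources used here. The submitters' processing notes name a mouse build, GRCm38, but the coordinates in the files are human: 55298 of the 62757 gene IDs were in GENCODE release 29, and 51535 of those had exactly its GRCh38 start and end. Coordinates are given in GRCh38, as the files hold them. The files also list 3945 gene IDs on alternate haplotype contigs. The deposited CPM values equalled each count scaled to the library's total, and the deposited RPKM values equalled that CPM divided by gene length in kilobases. Both were therefore left out of the tests, which used the deposited counts. Symbols came from a table that matched 54837 of the gene IDs. Where several IDs shared a symbol, the ID with the highest mean count was used. IDs without a symbol took between 0.245% and 0.253% of a library's counts.

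Total counts ranged from 19017552 to 22836948 per library. A gene with 0 counts in a library could have held up to 3 counts by chance, which is between 0.131 and 0.158 CPM at these depths and covers counting error only. Groups were taken from the sample titles. No pair of libraries in a group agreed within sampling noise: the chi-square of their counts per degree of freedom was between 1.82 and 3.05 within groups and between 19.8 and 22.9 across groups. No library was therefore merged with another as a duplicate, and each entered the tests on its own. This compares libraries with counting error only, which repeat preparations of 1 culture would also exceed, so it does not show separate cultures.

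The comparison of TRIM22 with vector was fitted in R 4.3.3 with edgeR 4.0.16. Genes passed the package's expression filter at a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM factors, and group was the only term of the model. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in the quasi-likelihood F test. Levels are CPM after TMM scaling. The SE of a gene's log2 fold change is the size of that change divided by the square root of the F statistic. There were 24 gene lists, fixed before the data were examined, and the test over lists was camera from limma 3.58.1, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 24 lists. Camera compares the members of a list with all other tested genes. Calls within a list were also counted with the p-values adjusted over the list alone. TRIM22 was in no list.

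The genes named were chosen by a rule also fixed beforehand. It took TRIM22, the 12 largest changes in each direction among called genes with a symbol, a mean of at least 1 CPM and no overlap between the groups' libraries, and the 2 called members per direction with the smallest adjusted p in each list. It also took TRIM5, TRIM6, TRIM34, STAT1, IFNB1, ISG15, VIM, CDH1, ZEB1, SNAI2, KRAS, DUSP6 and MYC whatever their result. The rule selected 113 tested genes. A gene named outside the rule is stated to be so.

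Alternatives fixed beforehand were RLE size factors, upper quartile scaling, library size only, TRIM22 left out of the library sizes, no count filter, a minimum of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, a minimum change of 2-fold, each library left out in turn, camera with an estimated correlation, and fry. After the data were seen, offsets for GC content with transcript length and offsets for the trend on abundance were added. The edgeR procedure was tested on simulated counts for the same 16062 genes and 6 libraries, with 50 genes changed at each of 4 sizes. It recovered 50% of genes changed 1.2-fold, 70% at 1.5-fold, 98% at 2-fold and 98% at 4-fold, with 11 false calls among 169 and none of 20 unchanged lists called. Genes were drawn independently, so the unchanged lists had no correlation between members. Estimated correlations in the data reached 0.44, for replication-dependent histone genes. Far fewer genes were changed than the 8118 called in the data, so these rates hold for the simulated setting only.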

Results

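Gene expression was measured in Capan-1, a human pancreatic ductal adenocarcinoma line established from a liver metastasis, which carries an activating KRAS mutation. Cells overexpressing TRIM22, an E3 ubiquitin ligase of the tripartite motif family that interferon induces, were compared with cells carrying an empty vector, with 3 libraries in each group. The series title places the experiment in work on KRAS-MAPK inhibition, interferon and epithelial-to-mesenchymal transition, and the comparison asks which genes TRIM22 overexpression moves. Total counts were 21572252, 22612111 and 22122201 in the vector libraries and 22435018, 19017552 and 22836948 in the TRIM22 libraries. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. A permutation test of 3 libraries against 3 cannot give a p below 0.1, so the tests relied on models that share the spread across genes. Levels are normalised CPM (counts scaled to library size and composition), as mean ± SD with n = 3 in each group.

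Genes of DNA replication and of cholesterol synthesis rose together in the TRIM22 cells, and genes of mitosis fell. All 32 DNA replication and G1/S genes were higher, by 1.39-fold at the median. In cholesterol synthesis 23 of 25 genes were higher, by 1.63-fold at the median, and 26 of 31 mitosis genes were lower, by 1.22-fold. The type I interferon response, the mesenchymal genes and the epithelial junction genes each held members that rose and members that fell, and camera called none of these 3 lists in the main analysis. Camera without a count filter and fry called the type I interferon response lower, and fry also called the mesenchymal genes lower. Individual genes with large changes included SPRR2A, which encodes a protein of the cornified envelope and rose 4.41-fold, and LGR5, a receptor that amplifies Wnt signalling, which fell 9.13-fold.

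TRIM22 itself (ENSG00000132274; chromosome 11, 5689689 to 5737089, plus strand) separated the groups as the labels do. It had 78, 71 and 73 counts in the vector libraries and 1363, 1183 and 1375 in the TRIM22 libraries. Its level was 3.32 ± 0.237 in vector cells and 61.8 ± 1.05 in TRIM22 cells, an 18.6-fold rise (log2 fold change 4.22, SE 0.08; adjusted p = 1.05e-39, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The counts do not separate transcripts of the introduced gene from those of the cells' own gene. TRIM5, which the annotation places across the same locus, was at 16.4 ± 1.05 and 15.9 ± 0.568 and did not pass the test (log2 fold change -0.04, SE 0.07). TRIM6 was at 1.57 ± 0.284 and 1.11 ± 0.105 and did not pass either (log2 fold change -0.49, SE 0.24). TRIM34 had 8 counts over the 6 libraries and was not tested.

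**Figure D1:**
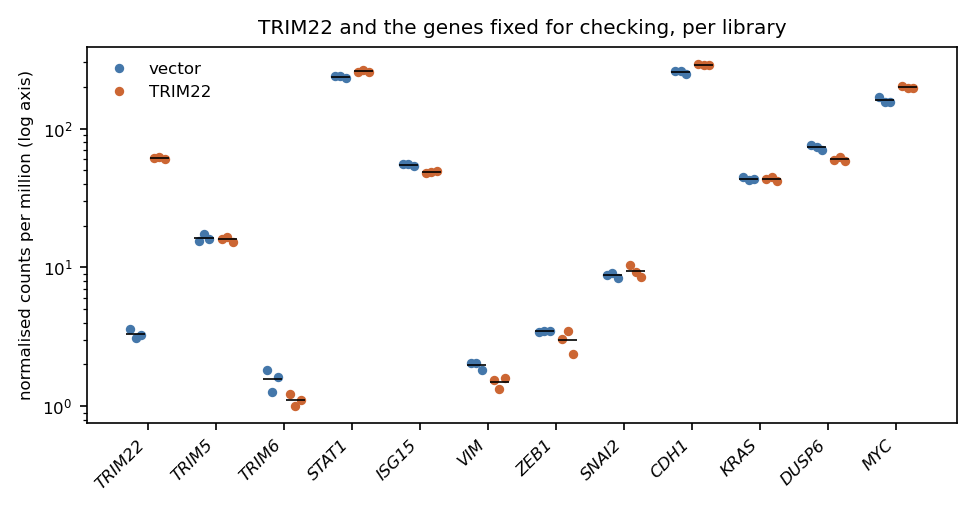
Normalised CPM (log axis) of TRIM22 and of 11 genes fixed before the data were examined, with one point per library and a black line at each group's mean. TRIM22 lay at 3.32 in vector and 61.8 in TRIM22 cells, far outside the spread of either group, and the other genes shown moved much less.

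Of 16062 tested genes, 4118 were higher and 4000 lower in TRIM22 cells, 50.5% in all (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most of these changes were small. The median change of a called gene was 1.24-fold, 90 genes rose and 538 fell by at least 2-fold, and 7609 of the called genes had no overlap between the groups' libraries. Over all tested genes 8952 had no overlap, where chance gives 10%. The direction followed abundance: among genes under 1 CPM 68 rose and 390 fell, and among genes over 64 CPM 1874 rose and 795 fell. Each vector library also had more genes with at least 1 count (26111, 26132 and 26312) than any TRIM22 library (25409, 24848 and 25538). The share of calls that were higher was 50.7%, and it depended on the scaling: it was 39.1% (3126 higher, 4870 lower) with upper quartile factors and 63.8% (5564 higher, 3156 lower) with offsets for GC content and length, which were added after the data were seen. The median log2 fold change over all tested genes moved too, from -0.0084 to -0.060 with upper quartile factors. It was -0.039 with library size only and 0.054 with those offsets. List medians shift with it, whereas camera compares a list with other genes. With upper quartile factors all 24 lists kept their camera direction and their call or lack of one.

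**Figure D2:**
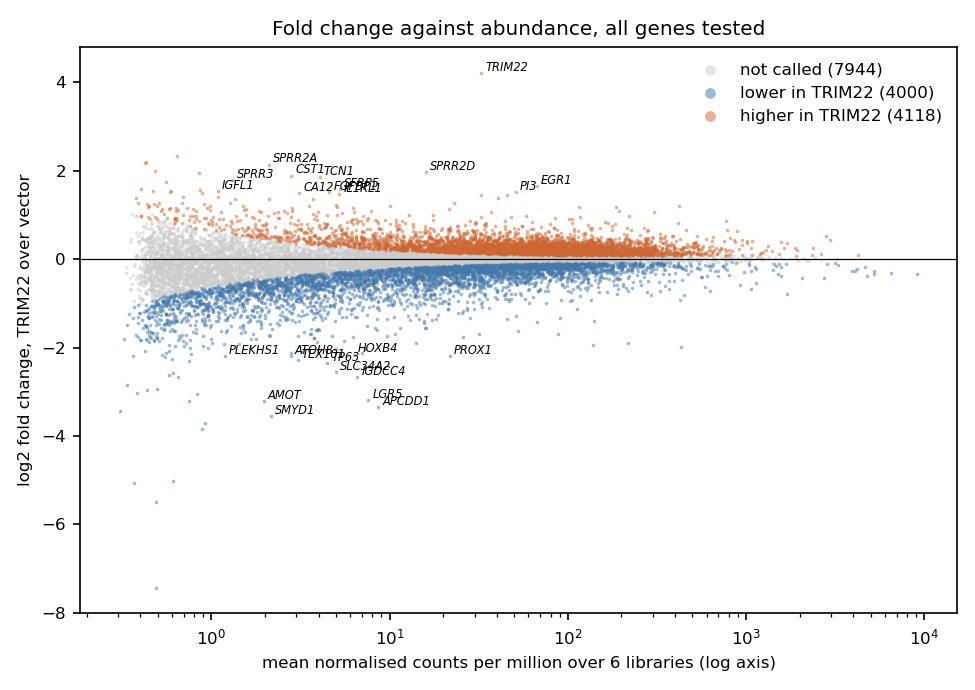
Log2 fold change of TRIM22 over vector against the mean normalised CPM over the 6 libraries (log axis), one point per tested gene, with higher genes in orange, lower genes in blue and genes not called in grey. The median log2 fold change was -0.28 among genes under 1 CPM and 0.08 among genes over 64, and TRIM22 stood at 4.22.

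The largest rises included 3 SPRR genes, which encode proteins of the cornified envelope. SPRR2A (chromosome 1, 153056113 to 153057537) rose from 0.778 ± 0.101 to 3.43 ± 0.212, and its neighbour SPRR2D (chromosome 1, 153039725 to 153041931) from 6.47 ± 0.201 to 25.4 ± 0.784. SPRR3, in the same gene cluster, rose 3.44-fold. PI3, which encodes the elastase inhibitor elafin, rose from 26.3 ± 0.960 to 75.6 ± 1.74. CST1, a secreted cysteine protease inhibitor, rose 3.71-fold, and TCN1, a vitamin B12 binding protein, 3.60-fold. EGR1, an immediate early transcription factor (chromosome 5, 138465490 to 138469315), rose from 32.3 ± 0.219 to 101 ± 5.31 (log2 fold change 1.65, SE 0.05; adjusted p = 1.58e-31, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). SFRP5, a secreted Wnt antagonist, rose 2.98-fold, IGFL1 2.89-fold, FGFBP1, a carrier of fibroblast growth factors, 2.87-fold, CA12, a carbonic anhydrase, 2.83-fold and IL1RL1, the receptor of interleukin 33, 2.77-fold. The SPRR2 genes and CST1 have close paralogs, and IL1RL1 overlaps IL18R1, so reads could be divided among them in ways the deposited counts do not show.

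LGR5, APCDD1 and PROX1 were among the largest falls. LGR5 (chromosome 12, 71439770 to 71586310) fell from 13.7 ± 0.443 to 1.48 ± 0.319, and APCDD1, a Wnt inhibitor (chromosome 18, 10454628 to 10489948), from 15.7 ± 1.12 to 1.54 ± 0.281. PROX1, a homeobox factor, fell from 35.6 ± 1.64 to 7.78 ± 0.689 (log2 fold change -2.20, SE 0.07; adjusted p = 9.70e-29, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). TP63, the p53 family factor of basal epithelium, fell 5.12-fold, ATOH8 4.54-fold and HOXB4 4.46-fold. SMYD1, a methyltransferase of muscle, fell from 3.96 ± 0.290 to 0.346 ± 0.261, and AMOT, an angiomotin that binds YAP, from 3.56 ± 1.22 to 0.374 ± 0.0976. IGDCC4 fell 6.34-fold, SLC34A2, a phosphate transporter, 5.88-fold, TEX101 4.86-fold and PLEKHS1 4.56-fold. LGR5 overlaps TSPAN8, PROX1 overlaps PROX1-AS1, and HOXB4 overlaps HOXB3 and HOXB-AS3, so without a stated strand setting their reads cannot be fully separated. Of the 12 genes, 11 lay under 16 CPM in vector cells, in the range where falls outnumbered rises over all genes.

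The type I interferon response, genes that interferon induces against viruses, leaned lower without passing the list test. Of its 42 measured genes 6 rose and 19 fell, and the counts adjusted over the list alone were also 6 and 19. STAT2, a subunit of the factor that drives these genes, fell from 78.0 ± 1.78 to 51.4 ± 1.31, and IFITM2, which blocks viral entry, fell 1.34-fold. OAS3, an activator of RNase L, rose 1.30-fold and DTX3L 1.14-fold. The largest falls of the list were IRF9 (2.12-fold), OASL (1.80-fold) and IFIT2 (1.78-fold), named after their values were seen. Each lay under 16 CPM in vector cells, where falls outnumbered rises over all genes. ISG15, a ubiquitin-like modifier, fell from 54.9 ± 1.12 to 49.0 ± 0.827, although its log2 fold change was 0.02 and not called with offsets for GC content and length. STAT1 rose from 237 ± 5.66 to 258 ± 4.40, a call that ended with upper quartile scaling (log2 fold change 0.07) and with offsets for abundance (0.05; adjusted p = 0.229 in edgeR). IFNB1, which encodes interferon beta, had 0 counts in all 6 libraries and was not detectable at this depth, which allows at most 0.158 CPM. The median log2 fold change of the list was -0.12 (camera, Benjamini-Hochberg adjusted p = 0.0763, and adjusted p = 0.161 with an estimated correlation). Without a count filter the median was -0.16 and the list was called lower (camera adjusted p = 0.0180), and with offsets for GC content and length the median was -0.04 (camera adjusted p = 0.131).

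Interferon genes outside that list also moved both ways. Among 20 measured genes of antigen presentation and interferon gamma response, 5 rose and 7 fell, with the same counts adjusted over the list alone. CD74, the invariant chain of MHC class II, fell from 462 ± 6.15 to 328 ± 8.97, and SOCS1, a feedback inhibitor of cytokine signalling, fell 2.55-fold, while the guanylate-binding protein GBP1 rose 1.35-fold. The median log2 fold change was -0.04 (camera, Benjamini-Hochberg adjusted p = 0.320) and turned to 0.0028 with offsets for abundance. Several genes of the MHC region had no or few counts: TAP1, TAP2, PSMB8, PSMB9 and HLA-E had 0 counts in 6 libraries and HLA-C had 2, while HLA-B had 397 and HLA-A 1417, against 8595 for B2M on chromosome 15, and the files list 2137 further gene IDs on alternate MHC haplotype contigs. These 9 genes were outside the naming rule and were named after their counts were seen. Of 16 interferon ligands, receptors and sensors measured, 5 rose and 3 fell (7 and 3 adjusted over the list alone; median log2 fold change 0.12; camera, Benjamini-Hochberg adjusted p = 0.417). CGAS, a sensor of cytosolic DNA, rose by 0.32 on the log2 scale and the kinase JAK1 rose 1.21-fold, while STING1, the adaptor downstream of CGAS, fell 1.18-fold and IFNAR1 1.11-fold. Among 13 TRIM genes near TRIM22 or induced by interferon, 3 rose and 4 fell over all genes and adjusted over the list alone (median log2 fold change -0.10; camera, Benjamini-Hochberg adjusted p = 0.435). TRIM14 rose 1.17-fold, TRIM25, a ligase of RIG-I signalling, 1.13-fold, and TRIM29 fell 1.39-fold.

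Mesenchymal genes of epithelial-to-mesenchymal transition were divided, with 9 of 28 measured genes higher and 12 lower, the same counts as adjusted over the list alone. CD44, the hyaluronan receptor, rose from 304 ± 2.99 to 531 ± 13.4, and LOXL2, a collagen crosslinking enzyme, 1.49-fold. TGFBI, a matrix protein induced by TGF-beta, fell from 451 ± 1.88 to 284 ± 4.66, and the tropomyosin TPM2 fell 2.09-fold. VIM was low in both groups, at 1.99 ± 0.131 and 1.49 ± 0.139, and did not pass the test. The transcription factors ZEB1 (3.48 ± 0.0352 and 2.99 ± 0.565) and SNAI2 (8.76 ± 0.330 and 9.41 ± 0.975) did not pass either. The list's median log2 fold change was -0.13 (camera, Benjamini-Hochberg adjusted p = 0.307), and it was 0.02 without a count filter and 0.03 with offsets for GC content and length.

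Epithelial junction and keratin genes were equally divided, with 12 of 40 measured genes higher and 12 lower, also when adjusted over the list alone. CDH1, which encodes E-cadherin, rose from 257 ± 8.64 to 290 ± 2.37 (log2 fold change 0.17, SE 0.03; adjusted p = 3.60e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). EPCAM rose 1.21-fold and the tight junction scaffold TJP2 1.23-fold, while claudin 1 (CLDN1) fell from 1342 ± 25.3 to 922 ± 13.3 and plakoglobin (JUP) fell 1.28-fold. The median and the mean of the list were slightly above 0 (log2 0.0070 and 0.0040), camera placed it slightly below other genes (Benjamini-Hochberg adjusted p = 0.795), and the median was -0.05 with upper quartile scaling and -0.02 with library size only. With offsets for GC content and length the median was 0.15 and camera placed the list above other genes (adjusted p = 0.301).

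TGF-beta targets fell as a list, with 2 of 22 measured genes higher and 12 lower, the same counts as adjusted over the list alone. BMP4, a ligand of the same superfamily, fell from 554 ± 27.5 to 292 ± 5.01, and TGFBI is also in this list. KLF10, a transcription factor that responds early to TGF-beta, rose 1.31-fold and the matricellular gene CCN2 1.59-fold. The other 8 were not called, among them SMAD7 (log2 fold change 0.11) and SERPINE1 (-0.16, under 1 CPM in both groups). ID1 (-0.63) and PMEPA1 (-0.43) were among the falls. SMAD7, SERPINE1, ID1 and PMEPA1 were named after their values were seen, and the activity of TGF-beta itself was not tested. The median log2 fold change was -0.18 (camera, Benjamini-Hochberg adjusted p = 7.26e-06, and adjusted p = 0.0331 with an estimated correlation) and -0.10 with offsets for GC content and length. YAP and TEAD targets went both ways, with 10 of 23 measured genes higher and 8 lower, also when adjusted over the list alone. F3, which encodes tissue factor, rose from 116 ± 6.10 to 208 ± 1.23 and CCN1 rose 1.70-fold, while ANKRD1 fell 1.82-fold and TGFB2 1.47-fold. The median log2 fold change of YAP and TEAD targets was 0.01 (camera, Benjamini-Hochberg adjusted p = 0.0763) and turned to -0.04 with upper quartile scaling. That list was called higher without a count filter (median log2 fold change 0.0052; camera adjusted p = 0.0140) and with offsets for GC content and length (0.12; camera adjusted p = 0.0200).

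The transcriptional output of the MAPK pathway was divided, with the larger changes upward. Of 27 measured genes 12 rose and 10 fell, with the same counts adjusted over the list alone. Epiregulin (EREG) rose from 258 ± 3.26 to 588 ± 11.9, amphiregulin (AREG) rose 2.74-fold, and EGR1 belongs to this list. Among inhibitors of the pathway, SPRY1 fell from 21.6 ± 0.628 to 12.4 ± 1.01 and the ERK phosphatase DUSP6 fell from 73.7 ± 3.09 to 60.0 ± 2.18, while ETV1, a transcription factor that ERK activates, fell 1.26-fold. Not every inhibitor fell: DUSP5, another ERK phosphatase, rose 1.97-fold and was named after its values were seen. The other falls were EPHA4 (log2 fold change -0.67), ETV5 (-0.24), CCND1 (-0.20), DUSP4 (-0.19), PHLDA1 (-0.19), SPRY4 (-0.18) and ETV4 (-0.11). These were also named after their values were seen. The members therefore give no single direction for the output of the pathway. MYC rose from 160 ± 6.56 to 198 ± 4.71. KRAS was at 43.6 ± 1.11 and 43.4 ± 1.35 and did not pass the test (log2 fold change -0.0094, SE 0.05). The list was called higher than other genes (camera, Benjamini-Hochberg adjusted p = 8.82e-06, and adjusted p = 0.0331 with an estimated correlation), with a mean log2 fold change of 0.20 and a median of 0.05, which was 0.0016 with upper quartile scaling. That scaling also lowered the median over all tested genes, from -0.0084 to -0.060, and the list stayed called higher.

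NF-kB targets moved both ways. CCL2, a monocyte chemoattractant, fell from 690 ± 62.8 to 173 ± 8.24 (3.99-fold, SE of the log2 fold change 0.04; adjusted p = 4.81e-37, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and CCL20 fell 1.88-fold. Interleukin 6 (IL6) rose from 11.6 ± 0.589 to 23.3 ± 1.86 and IL1A 1.51-fold. Of 27 measured genes 15 rose and 8 fell, also when adjusted over the list alone (median log2 fold change 0.15; camera, Benjamini-Hochberg adjusted p = 0.417). With offsets for abundance the median was 0.08 and camera placed the list below other genes (adjusted p = 0.977).

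Genes of the classical subtype of pancreatic cancer leaned lower and those of the basal-like subtype moved both ways. In the classical list 2 of 16 measured genes rose and 7 fell, also when adjusted over the list alone. TSPAN8, a tetraspanin, fell 1.94-fold and AGR2, a protein disulfide isomerase of mucus-producing cells, fell from 110 ± 4.56 to 74.1 ± 2.50, while the trefoil factor TFF1 rose by 0.58 on the log2 scale. The classical list was called lower (median log2 fold change -0.07, mean -0.25; camera, Benjamini-Hochberg adjusted p = 0.00310), but adjusted p = 0.0892 with an estimated correlation, and its median was 0.06 without a count filter. In the list of the basal-like subtype of pancreatic cancer 13 of 26 measured genes rose and 8 fell (14 and 8 adjusted over the list alone), with AREG and FGFBP1 among the rises and TP63 among the falls. TNS4, a tensin at focal adhesions, fell from 348 ± 19.6 to 209 ± 7.10. The basal-like median log2 fold change was 0.25 (camera, Benjamini-Hochberg adjusted p = 0.189), and the list was called higher without a count filter (camera adjusted p = 0.0331).

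The cell cycle lists moved apart. All 32 DNA replication and G1/S genes rose, also when adjusted over the list alone. CDC6, which loads the replicative helicase, rose from 204 ± 5.08 to 334 ± 6.53, and MCM4, a subunit of that helicase, from 216 ± 2.77 to 338 ± 2.23. As a list they were called higher (median log2 fold change 0.48; camera, Benjamini-Hochberg adjusted p = 4.24e-34, and adjusted p = 0.00183 with an estimated correlation). Of 31 mitosis and G2/M genes 26 fell and none rose (27 and 0 adjusted over the list alone). KIF20A, a kinesin of cytokinesis, fell 1.86-fold and the kinetochore protein CENPF from 131 ± 2.80 to 77.6 ± 2.79. This list was called lower (median log2 fold change -0.29; camera, Benjamini-Hochberg adjusted p = 2.22e-14, and adjusted p = 0.0238 with an estimated correlation). Every TRIM22 library showed both shifts, with list medians of 0.51, 0.50 and 0.52 for DNA replication and -0.30, -0.27 and -0.30 for mitosis relative to the mean of the vector libraries.

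**Figure D3:**
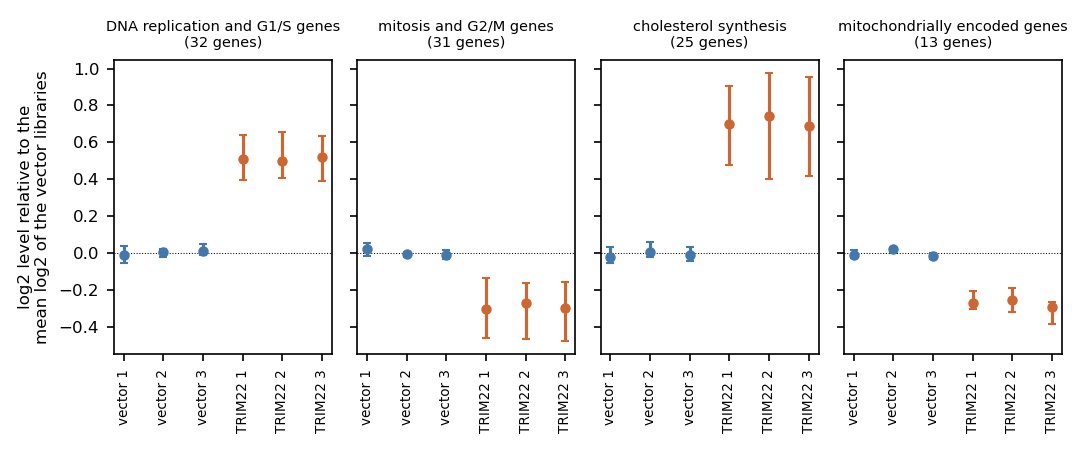
Median (point) and interquartile range (bar) of the members of 4 lists in each library, as the log2 level relative to each gene's mean log2 level in the vector libraries, with vector in blue and TRIM22 in orange. The TRIM22 libraries sat at 0.51, 0.50 and 0.52 for DNA replication, at -0.30, -0.27 and -0.30 for mitosis, at 0.70, 0.74 and 0.69 for cholesterol synthesis and at -0.27, -0.26 and -0.29 for mitochondrially encoded genes.

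Replication-dependent histone genes, as counted after oligo(dT) capture, did not rise as a list with the DNA replication genes. Of 10 measured 8 fell and none rose (8 and 1 adjusted over the list alone), with H2BC21 falling from 60.6 ± 3.46 to 35.0 ± 1.37 and H2BC12 from 69.1 ± 4.52 to 39.6 ± 2.95. The rise adjusted over the list alone was H4C3, from 13.1 ± 1.15 to 14.7 ± 0.630, and the list also holds H1-0, a linker histone made outside S phase, which fell 1.30-fold. Both were named after their values were seen. Most such transcripts lack a poly(A) tail, so oligo(dT) capture may miss them and the counts cannot show the full output of these genes. The counts of H2BC21, H2BC12 and the others may come from transcripts that have a tail. Whether those were made in S phase was not tested. Histone genes took 0.147%, 0.141% and 0.137% of counts in vector libraries and 0.0999%, 0.104% and 0.102% in TRIM22 libraries. Camera called the list lower (median log2 fold change -0.54; Benjamini-Hochberg adjusted p = 5.85e-08), but adjusted p = 0.144 with an estimated correlation. Among p53 targets 8 of 20 measured genes rose and 3 fell, also when adjusted over the list alone. The cyclin-dependent kinase inhibitor CDKN1A rose from 236 ± 3.49 to 328 ± 2.90 and the nuclease AEN 1.51-fold, while TP53INP1 fell 1.41-fold and FDXR 1.21-fold. That list was called higher (median log2 fold change 0.08; camera, Benjamini-Hochberg adjusted p = 0.0177), but adjusted p = 0.190 with an estimated correlation.

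Cholesterol synthesis had the largest median shift of the 24 lists. Of 25 measured genes 23 rose and none fell, also when adjusted over the list alone. SQLE, the squalene epoxidase, rose from 71.0 ± 3.93 to 161 ± 6.09, and DHCR24, which reduces desmosterol to cholesterol, from 198 ± 2.76 to 412 ± 6.29. Camera called the list higher (median log2 fold change 0.70; Benjamini-Hochberg adjusted p = 1.25e-41, and adjusted p = 0.00183 with an estimated correlation). Genes of hypoxia and glycolysis also rose as a list, with 17 of 28 measured genes higher and 5 lower, the same as adjusted over the list alone. Hexokinase 2 (HK2) rose from 41.4 ± 1.12 to 69.9 ± 0.925 and NDRG1 1.81-fold, while the glucose transporter SLC2A3 fell 1.95-fold. VEGFA fell from 306 ± 5.48 to 269 ± 3.48, a call that ended with offsets for GC content and length (log2 fold change -0.05). The median log2 fold change of the hypoxia and glycolysis list was 0.20 (camera, Benjamini-Hochberg adjusted p = 4.82e-05, and adjusted p = 0.0331 with an estimated correlation).

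Genes of the unfolded protein and integrated stress response rose more often than they fell. Of 29 measured genes 18 rose and 3 fell (19 and 4 adjusted over the list alone), with PPP1R15A, a phosphatase subunit that reverses translational arrest, rising from 83.7 ± 3.45 to 133 ± 0.803 and SDF2L1 1.31-fold. DDIT4, an inhibitor of mTORC1, fell 1.51-fold. Camera called this list higher (median log2 fold change 0.17; Benjamini-Hochberg adjusted p = 8.81e-04), but adjusted p = 0.145 with an estimated correlation. In the lysosome and autophagy list 6 of 28 measured genes rose and 10 fell (6 and 11 adjusted over the list alone). The autophagy receptor SQSTM1 rose 1.32-fold and the protease CTSL 1.31-fold, while GABARAPL1 fell 1.86-fold and CTSD fell from 330 ± 7.13 to 233 ± 6.51. The median of that list was 0.0047 on the log2 scale, its mean -0.07, and camera placed it below other genes (Benjamini-Hochberg adjusted p = 0.313); its median was -0.05 with upper quartile scaling, and it was called lower with offsets for abundance (camera adjusted p = 0.0466).

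All 13 mitochondrially encoded genes fell, also when adjusted over the list alone. MT-CYB fell from 5425 ± 94.5 to 4159 ± 122 and MT-CO3 1.27-fold, and the mitochondrial share of counts was 6.49%, 6.44% and 6.45% in vector libraries and 5.35%, 5.22% and 5.07% in TRIM22 libraries. Camera called them lower as a list (median log2 fold change -0.27; Benjamini-Hochberg adjusted p = 2.10e-07), but adjusted p = 0.161 with an estimated correlation. Of 31 cytosolic ribosomal protein genes 10 rose and none fell (8 and 0 adjusted over the list alone), with RPS7 rising by 0.26 on the log2 scale and RPL6 1.13-fold. Their median log2 fold change was 0.05 (camera, Benjamini-Hochberg adjusted p = 0.189) and turned to -0.0016 with upper quartile scaling. The cytosolic ribosomal protein genes were called higher without a count filter (camera adjusted p = 0.0318), without vector replicate 1 (camera adjusted p = 0.0281) and with offsets for GC content and length (camera adjusted p = 0.0119).

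Of 16 fibroblast and stromal markers 7 were measured, of which 5 fell and none rose (6 and 0 adjusted over the list alone). COL1A1 fell from 28.3 ± 1.04 to 19.7 ± 0.104 and the complement protease C1R 1.57-fold. Camera called these markers lower (median log2 fold change -0.53; Benjamini-Hochberg adjusted p = 0.0158), but adjusted p = 0.144 with an estimated correlation. Of 16 blood and endothelial cell markers 6 were measured, of which 1 rose and 2 fell (1 and 3 adjusted over the list alone). The actin-bundling gene LCP1 rose from 928 ± 6.47 to 1241 ± 16.4, while lysozyme (LYZ), also a classical subtype gene, fell 1.96-fold and PECAM1 1.72-fold. That list was not called (median log2 fold change -0.29; camera, Benjamini-Hochberg adjusted p = 0.728). Over the 24 lists camera called 12, and 6 of these held with an estimated correlation.

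**Figure D4:**
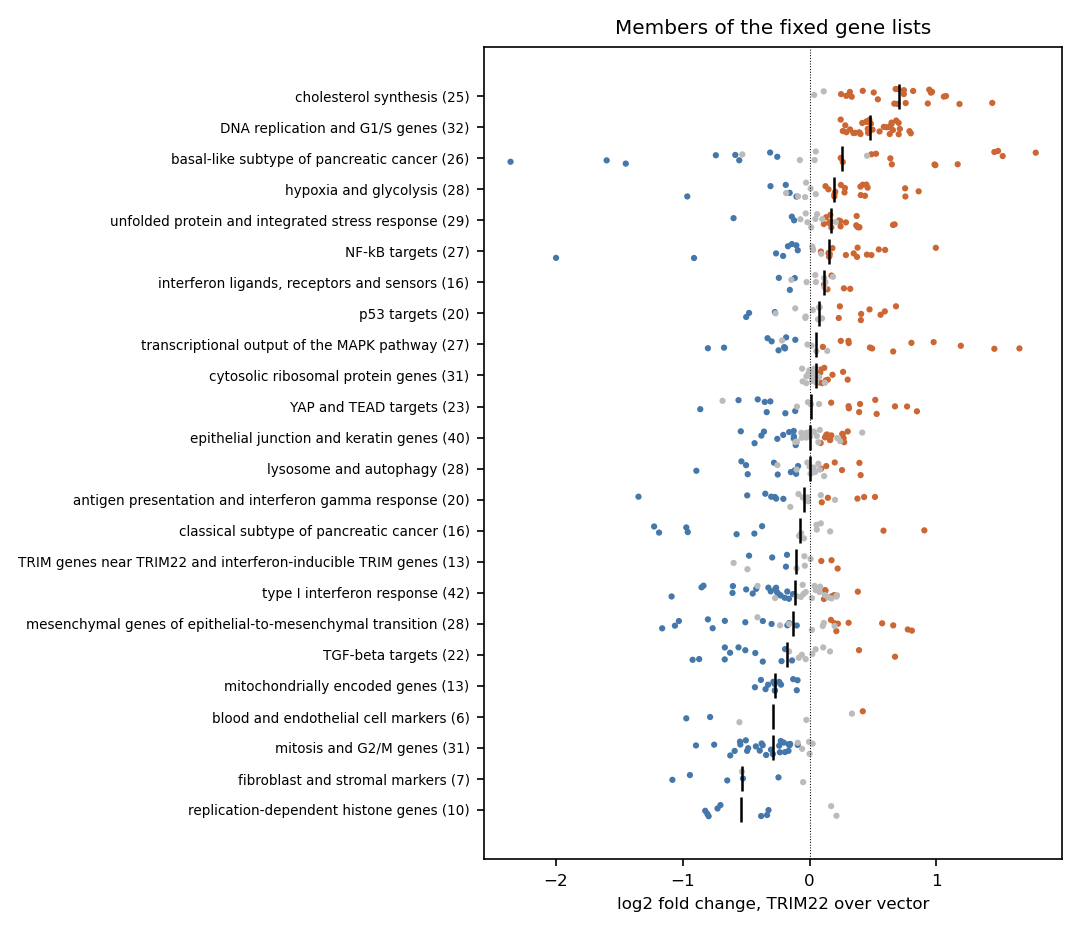
Log2 fold change of TRIM22 over vector for each measured member of the 24 lists (number of members in brackets), with higher genes in orange, lower genes in blue, genes not called in grey and a black line at each list's median. Cholesterol synthesis (median 0.70) and DNA replication and G1/S genes (0.48) lay farthest to the right, and replication-dependent histone genes (-0.54) and fibroblast and stromal markers (-0.53) farthest to the left.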

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

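The offsets for GC content with length and for abundance were chosen after the data were seen; the other alternatives were fixed before. The TRIM22 log2 fold change kept its direction and its call under every alternative run, between 4.16 and 4.27. Numbers of called genes stayed within 1.5 times of 4118 higher and 4000 lower, with 2 exceptions: DESeq2 called 2648 lower (and 3518 higher), and a minimum change of 2-fold left 90 higher and 538 lower by its construction; why DESeq2 called fewer was not tested. Leaving out 1 library at a time gave 3696 to 4046 higher and 3512 to 3855 lower genes. The replicate numbers gave no sign of pairing the libraries: same-numbered libraries deviated from their group means with correlations of -0.0052, 0.021 and 0.0056. Vector libraries 1, 2 and 3 matched TRIM22 libraries 2, 2 and 1 best. Counting noise could hide a weak shared signal here, so paired handling is not excluded. With the number as a block, 4063 genes were higher and 3948 lower. The type I interferon response was called lower without a count filter (median log2 -0.16, camera adjusted p = 0.0180, against 0.0554 to 0.161 under its other camera settings) and by fry (-0.12). Fry, which does not compare a list with other genes, also called the mesenchymal genes of epithelial-to-mesenchymal transition lower (-0.13) and 8 lists in all that camera did not call. The direction of camera turned for 2 lists, neither of them called: for epithelial junction and keratin genes without a count filter (median 0.015), with GC and length offsets (0.15) and without TRIM22 replicate 2 (leave-one-out medians 0.0035 to 0.026), and for NF-kB targets with abundance offsets (0.076). Among single genes, signs turned for ISG15 with GC and length offsets (0.019), for TRIM5 without vector replicate 2 (leave-one-out range -0.072 to 0.015) and for KRAS with DESeq2 (0.0047) and without vector replicate 1 or TRIM22 replicate 3 (leave-one-out range -0.027 to 0.017); the cause was not tested for any of these. Calls ended for CD274, FOXA2, VEGFA, PML, PHGDH and STAT1 under at least 1 alternative: FOXA2, under 1 CPM in both groups, lost its call without vector replicate 2 or 3 or TRIM22 replicate 1 or 3, CD274 without vector replicate 2 and PHGDH without TRIM22 replicate 1. TRIM6 was called lower without vector replicate 2 (-0.62, adjusted p = 0.0463 in edgeR). At these depths a gene with 0 counts could have held up to 0.158 CPM. A simulation on these 6 libraries, with far fewer changed genes than were called, recovered 50% of genes changed 1.2-fold and 98% changed 2-fold. The part of depth in this was not tested.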

Other observations

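Tests of whole chromosomes, of repeats of 1 culture, of background reads and of the immediate early, Wnt and cornified envelope lists were chosen only after the results they concern were seen. The 6 lists used here were written after the 24 fixed lists had been tested, so each is a hypothesis examined on the same libraries, and adjusted p-values are over these 6 lists. Members that had been seen before, because a fixed list held them or the naming rule selected them, were left out of the tests, a step added after the whole lists had been tested. The genes named from them were chosen after their values were seen. In this section the SE of a median, or of a difference of medians, was taken over the genes it covers. It treats those genes as independent and does not measure the spread between libraries. The SE of the coverage ratio given for background reads was taken between libraries instead.

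Whether the immediate early, Wnt and cornified envelope genes moved as classes stays open. Without the 4 Wnt and beta-catenin targets seen before, among them LGR5, APCDD1 and PROX1, 7 of 15 genes fell and 3 rose (median log2 fold change -0.145, SE 0.224; camera, adjusted p = 0.181 with an estimated correlation), against a median of -0.521 over the whole list. AXIN2, a feedback inhibitor that beta-catenin induces, fell by 1.86, while LEF1 rose by 0.55. Without the 10 cornified envelope and squamous genes seen before, among them SPRR2A, SPRR2D, SPRR3 and PI3, 4 of 14 rose and 4 fell (median -0.0318, SE 0.234; camera, adjusted p = 0.393 with an estimated correlation), against 0.484 over the whole list. Without the 11 immediate early genes seen before, 8 of 15 rose and 1 fell (median 0.262, SE 0.143, and camera adjusted p = 0.0867 with an estimated correlation), with EGR4 higher by 1.36. The criterion was set on the estimated correlation. With the preset correlation camera called these 15 genes higher (adjusted p = 0.0126). It did not call the remaining Wnt genes (camera adjusted p = 0.0684) or cornified envelope genes (camera adjusted p = 0.354). The whole lists were each called (camera, adjusted p = 0.00650, 0.0402 and 0.00650 with an estimated correlation), but they hold the genes that had prompted the tests.

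Fatty acid synthesis and desaturation genes, of which none had been seen before, rose in 13 of 19 cases and fell in 2 (median log2 fold change 0.413, SE 0.112). SCD, the stearoyl-CoA desaturase, rose by 1.09 on the log2 scale and FASN by 0.66, while SREBF1, which encodes a transcription factor of this pathway, fell by 0.45. With an estimated correlation camera gave p = 0.0192 unadjusted, adjusted p = 0.0289 beside the whole lists and adjusted p = 0.0577 beside the lists without members seen before, so the rise with cholesterol synthesis stays open. Nuclear-encoded genes of oxidative phosphorylation did not fall with the mitochondrially encoded ones in the main fit: 9 of 33 rose and 5 fell, with a median of 0.0293 (SE 0.0295, and camera adjusted p = 0.803 with an estimated correlation). Their median turned to -0.0408 with offsets for abundance and was 0.0978 with offsets for GC content and length.

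DNA replication genes rose while mitosis genes fell, a difference of 0.77 between the list medians. A trend on GC content and length is argued against as the whole cause, since the difference was 0.82 (SE 0.062) with offsets that remove it, and so is the trend on abundance, with a difference of 0.79 (SE 0.063). DNA repair and Fanconi genes, which are transcribed with the replication genes, rose in 20 of 25 cases and fell in none (median 0.302, SE 0.0382; camera, adjusted p = 0.0195 with an estimated correlation). The list of replication-dependent histone genes leaned the other way (8 of 10 lower, median -0.54), but it was not called with an estimated correlation (camera, adjusted p = 0.144). It holds H1-0, which is made outside S phase and was among the 8. Most such transcripts lack a poly(A) tail, so these counts cannot be set against the rise of the DNA replication genes. Whether the share of cells in each phase differed, and whether that followed from TRIM22 or from the growth state at harvest, was not tested.

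Genes of low abundance were lower in TRIM22 libraries, with a median log2 fold change of -0.23 under 4 CPM. Depth is argued against, since after thinning every library to the smallest total the lowest vector library still had 606 more genes detected than the highest TRIM22 library (573 before thinning), and with GC and length offsets the median was still -0.16 (SE 0.011). Background reads spread evenly over the genome are also argued against: the coverage per kilobase lost by genes with 100 to 200 counts was 1.59 times (SE 0.084) all the coverage of olfactory receptor genes in vector libraries, and those receptor genes kept 0.989 of their level. Among genes under 100 counts the ratio of TRIM22 to vector was 0.788 for protein-coding genes, 0.783 for lincRNAs and 0.776 for antisense genes, against 0.920 for processed pseudogenes. A larger amount of unspliced or nuclear RNA in the vector libraries, and a biological fall of weakly expressed genes in TRIM22 cells, were not tested and stay open.

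The number of called genes was large for changes this small. The real grouping called 8118 genes and the highest of the other 9 splits called 0 in edgeR (241 at an unadjusted p under 0.05). Each of those 9 splits mixes libraries of both groups, so the group difference inflates its spread and few calls would be made in any case. Only 1 of the 10 splits reached the real count, and 10 splits are too few for a share under 0.05. Gain or loss of whole chromosomes is argued against, since the largest chromosome median was 0.075 on the log2 scale (SE 0.027). Libraries of a group varied by a coefficient of 0.030 beyond counting error, and with labels that name no cultures, an effect of TRIM22 and a difference between 1 culture of each kind cannot be told apart.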
